A study of Aplysia californica with 8 samples.

How the data were processed

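RNA from cultured motor neurons of Aplysia californica, a marine mollusc with large neurons that can be grown and dissected singly, was measured on 4 two-colour Agilent arrays. Per the labels' protocols, neurons were grown for 4 days at 4 per dish, cell bodies or processes were removed by hand with glass microelectrodes, and the remaining RNA was extracted, amplified linearly over a pair of in vitro transcription rounds and labelled with Alexa Fluor 546 or Alexa Fluor 647. Each array carried 1 cell body sample and 1 process sample. By the labels all 4 cell body samples had the 546 dye and all 4 process samples the 647 dye, although the design text speaks of reciprocal hybridisation. Dye and compartment therefore cannot be told apart in these values, and no dye term was fitted.

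The deposited table holds 43693 features by 8 columns, 1 value per feature and channel, and each column was matched to its sample by identifier. The deposited values, which the authors made from Agilent Feature Extraction output per the submitters' processing notes, are treated as log2 intensities. No further step is named there, and the background correction, the normalisation and the log base are not given in the sources used here. The base was inferred from the values, which is an indirect basis: the cell body maxima lie between 15.9 and 16.4, close to the top of a 16-bit scanner's range on a log2 scale, and the process maxima lie between 16.8 and 17.2, above that range. Column medians lie between 5.11 and 5.21, the SD over features averaged 2.17 in cell body columns and 2.59 in process columns, and the median within-array difference lay between 0.02 and 0.04. Detection flags, background levels, spot saturation flags and scan dates were not used here, so the number of samples and the spread between them set the precision. Amplification before labelling can alter the relative levels of transcripts, and its effect was not measured.

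The features carry numbers from 12 to 45209, with 1505 numbers in that range skipped. None of them matched an identifier of the 21514 genes in the RefSeq table of assembly AplCal3.0, so no feature could be named by gene, and the planned tests per gene and per gene list were not made. Features are reported by number. Features may share a gene, so a count of features is not a count of genes.

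The direction throughout is process minus cell body. With the medians of the within-array differences all closer to 0 than the limit of 0.1 set beforehand, the deposited values were used without further normalisation. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 samples with the array as a block, which leaves 3 residual degrees of freedom and 1.14 prior degrees of freedom per feature. P-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The block was used because the labels name the shared array. The deviations of same-numbered samples from their group means correlated, across features, at r = -0.004, 0.107, 0.022 and -0.010 on arrays 1 to 4. On simulated data with the 43693 features' own means and spreads and 200 changed features, the fit recovered 44% of features changed by 0.5 on the log2 scale, 60% of those changed by 1, 84% of those changed by 2 and 82% of those changed by 3, with 8 false calls. The simulated noise was independent in every column, with no offset shared by an array or a channel. Far more than 200 features passed in the data, which loosens the adjusted threshold. The simulated rates and false calls therefore do not carry over to the reported fit.

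The design, the test, the rule for features named in the text and the first set of alternatives were fixed before the data were examined. The rule names, where no gene names are given, the 2 features per direction with the largest difference among those past the threshold with the same sign on all 4 arrays. The settings varied were no array block, loess within each array (span 0.3), median centring, quantile normalisation, leaving out the dimmest 25% or 50% of features, a variance trend, a minimum log2 difference of 1, array weights and leaving out each array. After the data were seen, classes of brightness were added, by the mean over all samples and with bright meaning a mean of 8 or more in at least 1 compartment, as were fits without repeated values, without features with any value under 3, without either and on features with a mean over all samples of 8 or more. A repeated value is defined as an exact value shared by 3 or more features of the same column. The labels describe the samples of a compartment as 4 biological replicates without saying whether they came from separate animals, so p-values measure only the spread between these samples.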

Results

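The study compared RNA in the cell bodies and in the processes (the neurites that extend from the cell body) of Aplysia motor neurons, 4 samples per compartment on 4 shared arrays, and asked which transcripts differ in level between these parts of the neuron. Process minus cell body differences below are on the log2 scale of the deposited values, whose base is inferred. By the labels the compartments also differ in dye on every array, so each difference is one of compartment and dye together.

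Samples of a compartment were close to each other and clearly apart from the other compartment. Across features, which are not independent replicates, Pearson's r ran from 0.978 to 0.989 between cell body samples, from 0.980 to 0.983 between process samples and from 0.831 to 0.885 between compartments. The first principal component held 85.1% of the variance and separated the 4 process samples, at 125 to 146, from the 4 cell body samples, at -148 to -111. Samples on the same array were no nearer to each other (mean r = 0.854 over 4 pairs) than samples on different arrays (mean r = 0.854 over 12 pairs). The within-array differences of any pair of arrays correlated across features at r = 0.884 to 0.901, so no array ran in the opposite direction to the rest.

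The brightest features differed more between compartments than between samples of a compartment. Single samples shared 890 to 958 of their 1000 brightest features within cell bodies, 932 to 954 within processes and 588 to 674 between compartments, so every overlap between compartments lay below every overlap within one. By the means of 4 samples, 622 of the 1000 brightest features were the same in both compartments, and 735 were when all features with a repeated value were left out. Probes differ in how strongly they bind their target, so brightness is not transcript abundance, and part of any overlap comes from the probes.

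**Figure D1:**
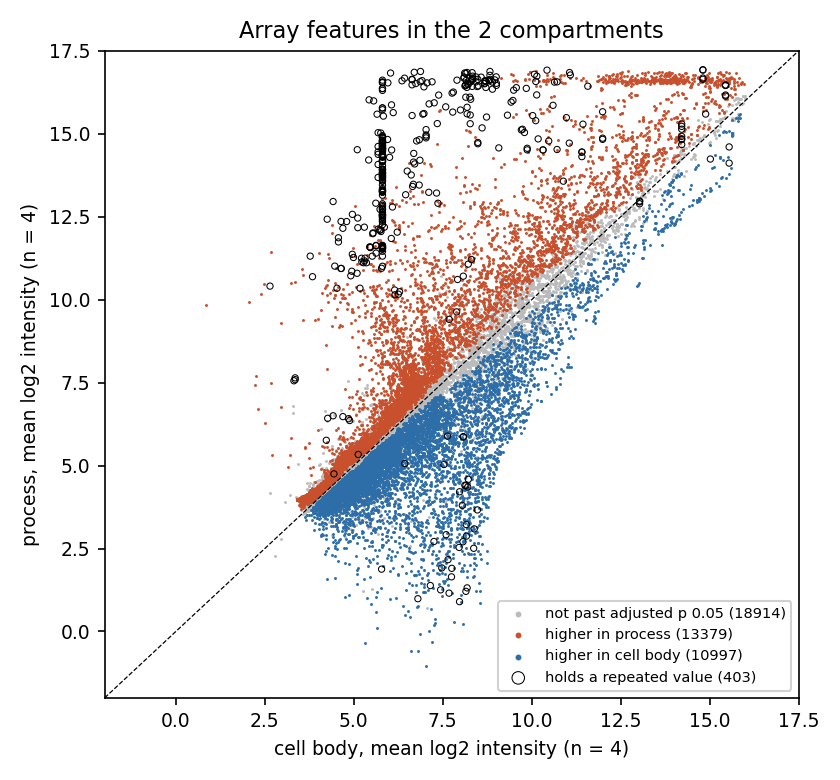
Mean log2 intensity of each of the 43693 features in cell bodies (x axis) and processes (y axis), n = 4 samples each, coloured by the limma call at an adjusted p of 0.05; the dashed line marks equal values and open circles, not coloured by call, mark the 403 features that hold a repeated value. A column of open circles stands at a cell body value near 5.80, and process values pile up above 16.

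Over all features, 24741 of 43693 (56.6%) differed between compartments at an adjusted p of 0.05 in limma, 13723 higher in processes and 11018 higher in cell bodies. This majority turned to 12055 against 13230 after loess within each array and to 7565 against 7999 without the dimmest 25% of features. The difference had the same sign on all 4 arrays for 24727 of the 24741. A test on 4 within-array differences nearly forces this for any call, so it is no separate support. Over all features the sign was shared for 69.0%, where chance gives 12.5% only if the arrays share no offset between the channels. A difference of at least 1, that is 2-fold, was found for 6476 features, 3240 higher in processes and 3236 higher in cell bodies as deposited, but 2188 and 4298 after loess within each array and 2447 and 4205 after quantile normalisation, so this even split depends on the scaling. At 16-fold or more, 742 were higher in processes and 396 higher in cell bodies, and 421 and 380 without features that hold a repeated value. Leaving out repeated values lowers the process count by itself. Of the 372 features with a repeated cell body value, 344 were called higher in processes and 3 higher in cell bodies. Leaving out features with any value under 3 as well gave 388 and 68, but that step mostly removes features for a low process value and so lowers the cell body count by itself. At 64-fold or more the counts were 373 and 53 with all features, 107 and 48 without repeated values and 87 and 0 without either.

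In the values as deposited, the direction of the differences varied with brightness, taken as the mean over all 8 samples. Among the 708 features with a mean of 14 or more, 548 were higher in processes, 43 were higher in cell bodies and 117 did not pass the threshold, with a median difference of 1.59 (quartiles 0.51 and 2.90). Among the 2654 features with a mean of 8 to 10, 1065 were higher in processes and 636 higher in cell bodies, with a median difference of 0.25. Features between 6 and 8 showed 2-fold differences more often toward cell bodies, 1156 against 785. The 30924 features under 6 gave 16275 calls, of which 54 were at least 2-fold higher in processes and 1398 at least 2-fold higher in cell bodies, and the median size of a called difference there was 0.29. Replicates were tight at that level, with a median SD (n = 4) of 0.033 in cell bodies and 0.075 in processes, against 0.219 and 0.158 in the brightest class. The process columns were also the wider ones, with an SD over features of 2.59 against 2.17.

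**Figure D2:**
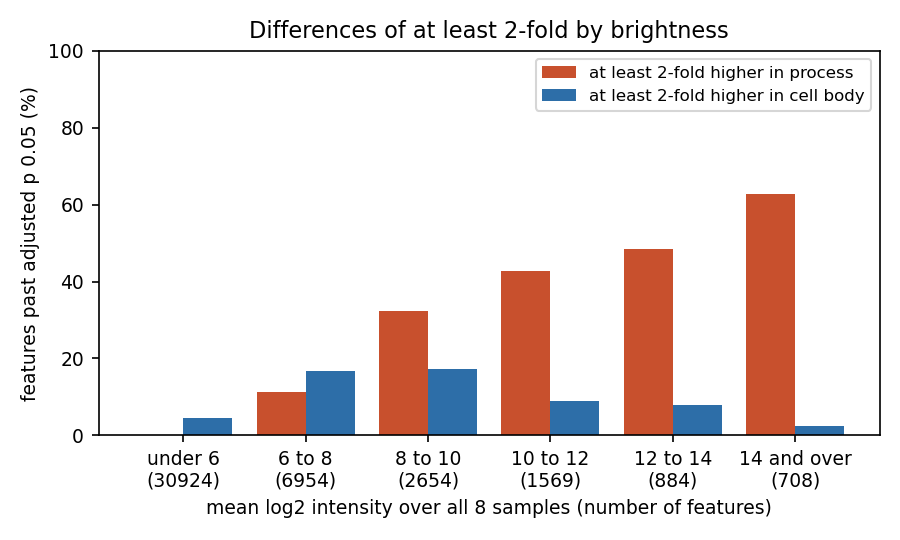
Percent of features that passed an adjusted p of 0.05 in limma with a difference of at least 2-fold (y axis), by the mean log2 intensity over all 8 samples (x axis, with the number of features), for features higher in processes and higher in cell bodies. In the brightest class 444 of 708 features were at least 2-fold higher in processes and 18 in cell bodies, whereas between 6 and 8 the numbers were 785 and 1156 of 6954.

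The preponderance of process-higher features among bright ones depended on the scaling of the arrays. Of the 7325 bright features, 3659 were higher in processes and 1787 higher in cell bodies as deposited, a share of 67.2% of calls, and 65.2% among the 6950 of them without a repeated value. After loess within each array the share was 46.2%, with 2523 higher in processes and 2938 higher in cell bodies, and after quantile normalisation it was 41.9%, with 2383 and 3298. Median centring left it at 66.5%. Membership in this set follows the brighter compartment; among the 5815 features with a mean over all samples of 8 or more, the share was 74.8% as deposited, 47.7% after loess and 41.4% after quantile normalisation. The median difference of bright features moved from 0.62 as deposited to -0.28 after loess and -0.44 after quantile normalisation. Over all features the share of calls higher in processes was 55.5% as deposited, 47.7% after loess and 62.6% after quantile normalisation. Of the features called as deposited, 20876 kept their call and direction after loess and 410 were called in the opposite direction.

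**Figure D3:**
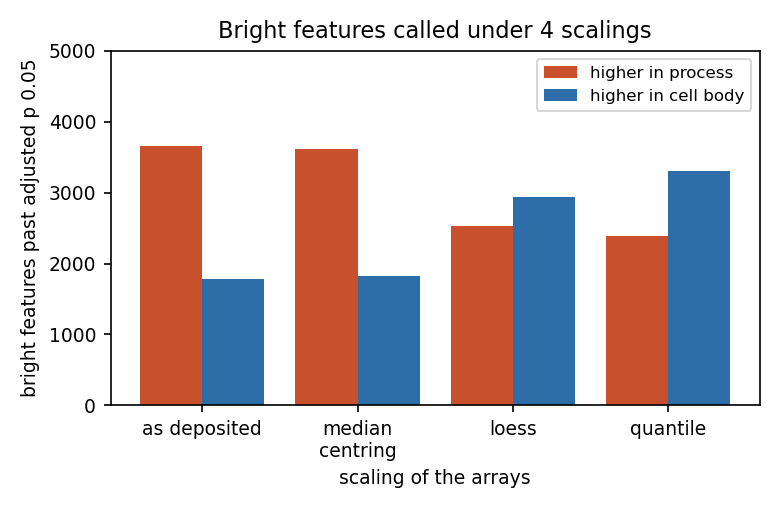
Number of bright features past an adjusted p of 0.05 in limma (y axis), higher in processes or in cell bodies, under 4 scalings of the arrays (x axis). Process-higher features outnumber cell-body-higher ones as deposited (3659 against 1787) and after median centring, and are outnumbered after loess (2523 against 2938) and quantile normalisation (2383 against 3298).

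The features named by the fixed rule stand at the extremes of the process channel. In cell bodies their means lie between the 65.7th and the 86.8th percentile. Feature 19039 was at 16.6 ± 0.0947 (SD, n = 4) in processes and 5.80 ± 0.0053 in cell bodies, a difference of 10.81 with a 95% interval of 10.68 to 10.93 and a limma adjusted p of 4.02e-05. All 4 of its cell body values are repeated values. Feature 36215 was at 16.8 ± 0.124 in processes and 6.03 ± 0.453 in cell bodies (difference 10.80, interval 10.19 to 11.41, limma adjusted p = 0.000214), and 3 of its 4 cell body values are repeated. These repeated values are each shared exactly by at least 123 features of their column, so they are unlikely to be readings of these features alone. In the other direction, feature 20919 was at -1.05 ± 1.30 in processes and 7.04 ± 1.23 in cell bodies (difference -8.10, interval -8.57 to -7.62, limma adjusted p = 0.000231). The SE of this difference was 0.17 with the array block and 0.82 without it, so the narrow interval rests on the block. Feature 20772 was at 0.22 ± 2.58 in processes and 8.08 ± 0.641 in cell bodies (difference -7.86, interval -10.66 to -5.06, limma adjusted p = 0.00496). The process values of feature 20919 on all 4 arrays, and of feature 20772 on 3 arrays, lie under 3, within the lowest 1% of the process columns, which ends at 3.06 to 3.25. No background level stands beside these values, so no fold is read from any of the 4 features, and the intervals describe only the spread of the deposited values.

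**Figure D4:**
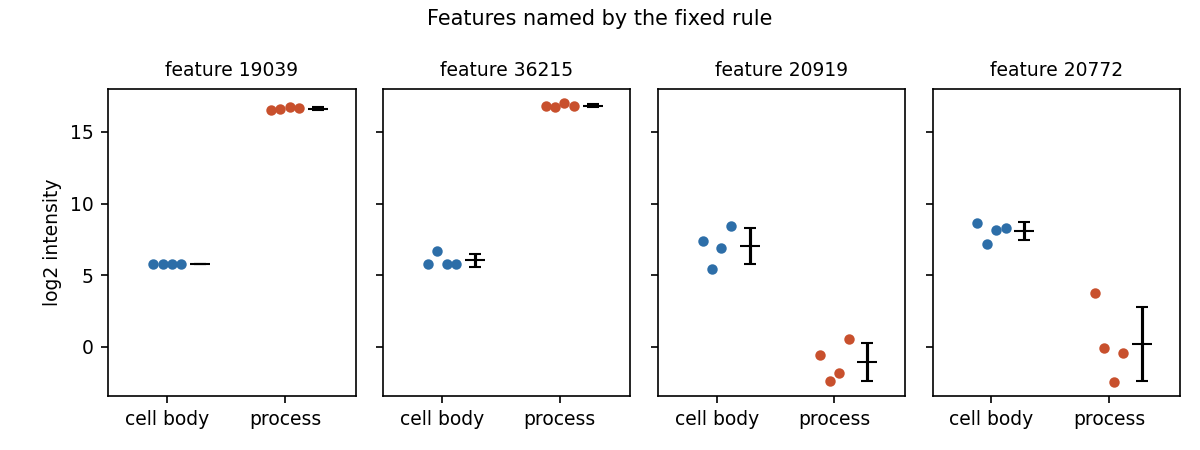
Log2 intensity (y axis) of the 4 features named by the fixed rule in each cell body and process sample (points), with the mean and SD of 4 samples beside them. Features 19039 and 36215 lie near 16.6 and 16.8 in processes with repeated cell body values near 5.80, and features 20919 and 20772 lie at -1.05 and 0.22 on average in processes.

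The same held for larger sets. Of the 50 largest differences toward processes, 49 included a repeated cell body value, and of the 50 largest toward cell bodies, all 50 included a process value under 3. Among features with no repeated value and no value under 3, a set defined after the data were seen, the largest difference toward processes was 8.31 (SE 0.95, limma adjusted p = 0.00356), from 7.41 ± 2.00 (SD, n = 4) in cell bodies to 15.7 ± 0.359 in processes. The 20 largest of that set ranged down to 6.90. Toward cell bodies the largest difference was -5.00 (SE 0.16, limma adjusted p = 0.000388), from 8.76 ± 0.133 in cell bodies to 3.76 ± 0.455 in processes, and the 20 largest ranged to -4.52; the limit of 3 itself restricts the size of differences in this direction.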

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

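Of the tests in this part, the search for repeated values, their position in the columns, the comparison without them and the test of offsets shared at equal brightness were chosen after the data were seen, as was the class of bright features. Of 29 measures, taken per sample or per array and tested for 1 value far from the other 3, 3 stood out. Chance gives about 1 in 20 for a single independent measure. The measures overlap and include the features named for their extreme differences, so that rate is only a rough guide. Cell body replicate 3 held 28 values of 16 or more, and the other cell body samples held 0 or 1. Feature 36215 stood at 6.71 in cell body replicate 2, where the other 3 samples hold the repeated value of their column, and at 17.01 in process replicate 3, against 16.7 to 16.8 in the other process samples. Beside such near-identical repeated values, almost any unshared value would stand out.

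The first pattern is the repeated cell body value. In cell body replicates 1 to 4 an exact value (5.80, 5.80, 5.81 and 5.80) was shared by 199, 123, 168 and 215 features, against at most 18 features sharing any value in a process column. Repeats made up 0.023% of cell body values where the process value was under 8, but 17.6% ± 2.8 (SD, n = 4 arrays) where it was 14 to 16 and 12.9% ± 5.4 where it was 16 or more. Separate readings would hardly give 1 exact value at 123 to 215 features, so the ties argue against each being its feature's own reading. The shared value lies just under the column means, which are 5.85 to 5.86. Whether a dim signal lies behind it stays open. The repeated value lies at the 65.6th percentile or higher of its column, but 30924 of the 43693 features have a mean over all samples under 6. That position therefore cannot tell a dim reading from any other. Whether values were filled in before deposit stays open: the number of features sharing a value, at least 123 in each cell body column, is the observation itself and no separate test of it. For 108 features that hold it on some arrays and an unshared value on others, the median difference on the latter arrays was 6.62. Features equally bright in processes had 1.18 (excess 5.13, 95% bootstrap interval 4.34 to 5.50). The transcripts of the 108 may therefore be low in cell bodies relative to processes. Their median cell body value on those arrays was 7.88, above the repeated values near 5.80, so the repeated values may overstate the difference. How low stays open, since unshared values could have been filled in too. The 108 features were read on the same 4 arrays and are not independent replicates, so the interval may understate the spread between samples.

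The second pattern is the excess of process-higher calls among bright features. Repeated values are not its whole cause, since the share stayed at 64.0% when bright features without them were fitted alone. A channel difference that varies with intensity stays open: the share fell to 46.2% after loess, but loess centres the differences at each brightness whatever their origin. Dye and compartment cannot be told apart because the labels give only 1 dye orientation, and a biological difference between compartments stays open for the same reason.

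The third pattern is the large number of calls among features that are not bright, 19295 of the 24741. Offsets shared by features of equal brightness are not the whole of it, since loess within each array, which removes them, changed the number of these calls by a factor of 1.03, and by 0.95 to 1.04 with each array left out. Small offsets that differ between features stay open. As deposited, 88.8% of these calls differed by under 1 on the log2 scale, close to the limit of 90% set beforehand. The share was above that limit after quantile normalisation (90.1%) and without features with any value under 3 (91.0%). It was also above it without features with a repeated value or any value under 3 (91.0%). Under every other setting with such calls it was below, from 75.8% without the dimmest 50% of features to 89.5% without the array block. The share fell on either side of the limit by setting, mostly below it, so it decides nothing. A biological difference between compartments stays open as well, untested apart from dye. Among the lowest-numbered features, called features with a mean under 6 were mostly higher in cell bodies. The whole class under 6 was split, with 8246 higher in processes and 8029 higher in cell bodies. The direction of dim calls may therefore vary with feature number, which loess on brightness would not remove. That was not tested, so the number of dim calls cannot be taken as biological.

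With the array block, 1 of the 32 splits of the 8 samples that can be fitted, the real one, gave as many as 24741 calls, and the highest of the others was 0. Without the block it was 1 of 35 splits, with 26868 calls and at most 1 in any other. In both sets the other splits leave the compartment difference in the residual spread, which by itself lowers their counts, and most of them break the pairing by array. The 8 splits that part every array keep the pairing but leave the same difference in the residual spread of all but the real one. Among these the real one gave 24741 and the highest other 0, and 8 splits are too few for a share under 0.05. These counts do not bear on dye, which follows the real split.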

How the results depend on the processing

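The fits without repeated values, without values under 3 and on brighter features only were chosen after the data were seen. Calls fell with fewer features tested: to 15564 (7565 higher in processes, 7999 in cell bodies, so the majority turned) without the dimmest 25%, to 11188 (6308 higher in processes, 4880 in cell bodies) without the dimmest 50%, to 5509 on bright features only (3648 and 1861, with 1485 at least 2-fold higher in cell bodies) and to 5180 on bright features without repeated values (3317 and 1863, with 1479 at least 2-fold higher in cell bodies). On features with a mean over all samples of 8 or more it was 4097 (3037 and 1060, with 741 at least 2-fold higher in cell bodies). A minimum log2 difference of 1 left 6476 (3240 and 3236). Over all features, median centring gave a near-even 12494 higher in processes and 12152 in cell bodies, loess 12055 and 13230, and quantile normalisation 17117 and 10224. At least 2-fold, the counts were 3180 and 3349 after median centring, 2188 and 4298 after loess and 2447 and 4205 after quantile normalisation. Scaling changed the bright split: cell-body-higher bright features numbered 2938 after loess and 3298 after quantile normalisation, and process-higher ones 2383 after quantile normalisation; whether dye or compartment causes this was not tested. Leaving out each array gave 19326 to 21554 calls, 10662 to 12169 higher in processes and 8519 to 9385 in cell bodies; at least 2-fold, 3067 to 3222 and 2930 to 2950. Without the replicate block, that is without pairing samples by array, 26868 features passed, 24374 of them called in the same direction with it. The variance trend gave 25734 calls and array weights 25597. The lowest correlation between arrays' differences was 0.868 after loess, 0.867 after quantile normalisation, 0.895 without the dimmest 50%, 0.869 without repeated values, 0.863 also without values under 3, 0.911 on bright features, 0.901 on those without repeated values and 0.8996 on features with a mean over all samples of 8 or more. The 4 named features kept their sign and call under every alternative that tested them. The planned fits per gene and per gene list were not run, since no feature was named. No background level was used, so what is undetected in a compartment cannot be stated.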

Other observations

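All comparisons in this part were chosen after the data were seen. Cell body replicate 2 lay nearer to the process samples than the other cell body samples did, at -111 on the first principal component against -148 to -140. Over the 1121 features without repeated values that were at least 4-fold higher in processes and had a process mean of 10 or more, its value lay a median of 0.37 above the mean of the other cell body samples, and it was the highest cell body sample for 57.1% of them. The same deviation was -0.03, -0.13 and -0.14 for replicates 1, 3 and 4. Over the 719 features without repeated values that were at least 4-fold higher in cell bodies and had a cell body mean of 8 or more, replicate 2 lay a median of 0.11 below the others, its deviation being -0.11. Without array 2 the fit called 19759 features.

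Process columns held 507 to 560 values of 16 or more and 232 to 260 between 15 and 16, while cell body columns held 0 to 28 and 163 to 224. Process values under 3 numbered 337 to 407 per array and cell body values under 3 numbered 18 to 42. Of the 660 features with any process value under 3, 588 were at least 2-fold higher in cell bodies, and the median cell body mean of the 660 was 7.04. Picking features for a low process value favours that direction by itself. Of the 88 features with any cell body value under 3, 0 were called higher in cell bodies.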
